A study of Homo sapiens with 11 samples.

How the data were processed

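RNA was sequenced as paired ends from 11 libraries of the lines OCI-AML3 and OCI-AML3-FLT3-ITD. They were controls or exposed to 100 nM FHD-286 for 16 h, per the labels. Controls are called untreated below, although the labels do not say whether they received a vehicle. Total RNA was DNase treated before library construction, per the labels' protocols. The authors deposited raw counts per gene for 58037 Ensembl identifiers, as whole numbers that were not normalised. Reads were aligned with STAR to hg38, per the submitters' processing notes. The counting program, its strand setting and the annotation were not given in the sources used here, so reads of overlapping and antisense genes cannot be told apart. For named genes the share of exon length that overlaps another gene was computed, and shares above 10% are stated where a gene carries a list. Of the identifiers, 57388 were found in GENCODE 29 on GRCh38, from which coordinates were taken, and 56948 had a symbol. Counts of multi-copy families such as histone and ribosomal protein genes may be split between near-identical copies by the counting and are uncertain in that respect.

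Total counts ran from 58397190 to 79172389 per library. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 18908. Counts were scaled by TMM factors and fitted with edgeR 4.0.16 in R 4.3.3 by a quasi-likelihood model with 1 mean per group and 1 shared spread, with 7 residual degrees of freedom. The contrasts were FHD-286 against control in each line, the difference between these effects, and untreated FLT3-ITD against untreated OCI-AML3. All tests were two-sided. SE is the size of the log2 fold change divided by the square root of the quasi-likelihood F statistic, an approximate standard error. Adjusted p-values are Benjamini-Hochberg over all genes tested, with a threshold of 0.05, and CPM are normalised by the same factors. The common biological coefficient of variation was 0.193 with all libraries and 0.0652 without the library labelled OCI-AML3-FLT3-ITD control replicate 2.

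Groups, contrasts, 26 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. FLT3, SMARCA4, SMARCA2, MYC and SPI1 were named in every comparison. Further names were the 10 largest changes in each direction (6 for the difference between lines) among called genes with an average log2 CPM of at least 2 and, except for the difference, CPM ranges that did not overlap. Statements below of the largest changes or differences hold among genes that met this rule. In each list described, the 3 members with the smallest p and 1 member of the minority direction could be named. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. List members were also adjusted over the list alone.

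The model was tested on simulated counts with 200 changed genes. These were drawn only from genes with a positive average log2 CPM, so recovery of genes with lower counts was not tested. For OCI-AML3 it recovered 78% of 100 genes changed 2-fold and 96% of 100 changed 4-fold, with 5 unchanged genes called among 18371. For the FLT3-ITD line it recovered 77% and 99%, with 12 unchanged genes called among 18376. For the difference between lines it recovered 44% and 90%, with 9 called among 18347. For the untreated lines it recovered 71% and 98%, with 5 called among 18338. The data gave more calls than the 200 simulated changes, at 7816, 5767, 635 and 5289 for the comparisons in this order. Recovery was not tested with a library that departs from its group, as that labelled OCI-AML3-FLT3-ITD control replicate 2 does. These shares and false calls therefore describe the simulated counts and may not hold for these libraries.

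The alternatives were other scalings (DESeq2 size factors, upper quartile, library totals), no filter or a stricter one (CPM of at least 1 in at least 3 libraries), the Wald test of DESeq2 1.42.0, a fit of only the groups compared, the replicate number as a block, a minimum log2 fold change of 1, and leaving out each library. Values of gene lists without the library labelled OCI-AML3-FLT3-ITD control replicate 2 with an estimated correlation were added after seeing the data. Fold changes of named genes with 1 to 3 counts in a group are given as ratios with a 95% exact binomial interval, which covers counting error only.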

Results

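Gene expression was measured by paired-end RNA sequencing in 11 libraries from a pair of human acute myeloid leukaemia (AML) lines. OCI-AML3 is an established AML line, and OCI-AML3-FLT3-ITD is the line named in the labels for the internal tandem duplication of FLT3, a receptor tyrosine kinase of blood progenitors. Cells were exposed to 100 nM FHD-286 for 16 h or left as controls. FHD-286 is an inhibitor of BRG1 and BRM, the ATPases of the BAF chromatin remodelling complex encoded by SMARCA4 and SMARCA2. The groups were OCI-AML3 control (n = 3), OCI-AML3 with FHD-286 (n = 3), OCI-AML3-FLT3-ITD control (n = 3) and OCI-AML3-FLT3-ITD with FHD-286 (n = 2).

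Total counts were 58397190, 67165554 and 61856368 in OCI-AML3 control replicates 1, 2 and 3, and 72043797, 73925167 and 75031633 in the treated OCI-AML3 replicates. They were 73144344, 69180721 and 79172389 in the OCI-AML3-FLT3-ITD control replicates and 68820021 and 75867647 in the treated ones. At these depths 3 counts in a library corresponded to between 0.0366 and 0.0548 normalised CPM (library-size-scaled counts), a limit that covers counting error only. Nothing in the labels says that replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

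FLT3 (ENSG00000122025.14, GRCh38 chromosome 13, 28003274 to 28100592) set 1 library apart from its label. Its level was 178 and 203 CPM in OCI-AML3-FLT3-ITD control replicates 1 and 3, 171 and 169 CPM in the treated FLT3-ITD libraries, and 53.4 CPM in the library labelled OCI-AML3-FLT3-ITD control replicate 2, against 42.0 ± 1.16 CPM (SD, n = 3) in OCI-AML3 controls. WLS, a carrier protein for Wnt ligands, was at 13.5 and 14.4 CPM in FLT3-ITD control replicates 1 and 3 and at 0.058 CPM in that library, and WT1, a transcription factor often raised in AML, was at 21.8, 19.9 and 0.20 CPM. Across genes, which are not independent replicates, that library's log CPM correlated at 0.957 and 0.960 with the other FLT3-ITD controls. Those controls correlated at 0.993 with each other. With the OCI-AML3 controls that library correlated at 0.979 to 0.984, below the 0.992 to 0.993 among them. Mitochondrially encoded genes took 8.85% of its counts, against 4.48% to 7.54% in the other libraries. It was kept in its labelled group, and values without it are given beside those it moves.

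**Figure D1:**
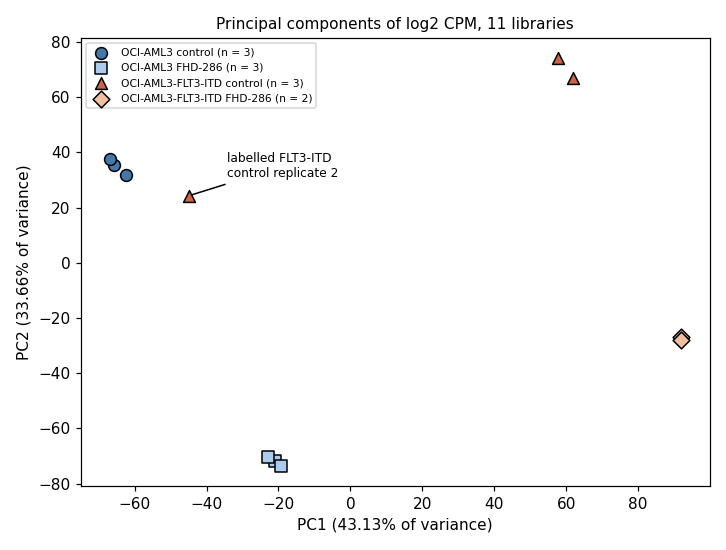
Principal components 1 (43.1% of variance) and 2 (33.7%) of log2 CPM, 1 point per library, with colour and shape giving the labelled group. The library labelled OCI-AML3-FLT3-ITD control replicate 2 lies at -45.0 on component 1, near the OCI-AML3 controls (-67.0 to -62.4) and away from the other FLT3-ITD controls (57.6 and 61.9). On component 3 (8.21% of variance, not drawn) it lies at -75.7, apart from all other libraries (-8.57 to 33.5).

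FHD-286 lowered MYC and SPI1 in OCI-AML3. MYC, the growth-driving transcription factor (ENSG00000136997.15, chromosome 8, 127735434 to 127741434), fell from 822 ± 45.5 to 224 ± 7.47 CPM (SD, n = 3 and 3; log2 fold change -1.87, SE 0.10). SPI1, which encodes the myeloid transcription factor PU.1 (ENSG00000066336.11, chromosome 11, 47354860 to 47378576), fell from 320 ± 22.4 to 44.5 ± 4.02 CPM (log2 fold change -2.84, SE 0.09). SMARCA4 fell by 0.31 on the log2 scale, from 472 ± 39.3 to 381 ± 2.99 CPM. SMARCA2 had a log2 fold change of 0.15 and FLT3 one of -0.02, and neither passed the test. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 4.6e-07 for MYC, 2.47e-08 for SPI1 and 0.0142 for SMARCA4, against 0.145 for SMARCA2 and 0.975 for FLT3.

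**Figure D2:**
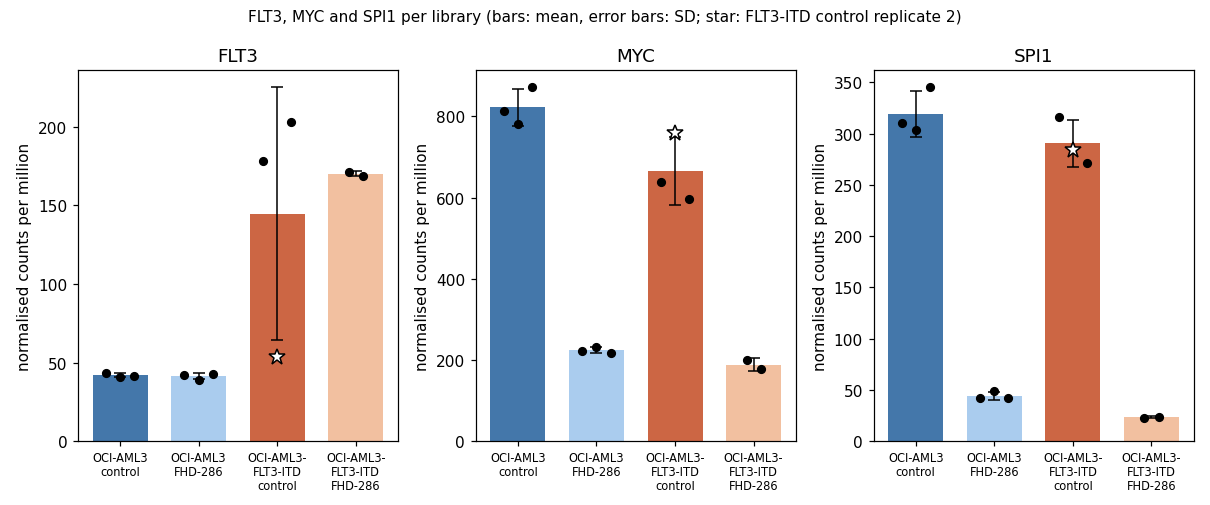
Normalised CPM of FLT3, MYC and SPI1 in each library (points), with group means (bars) and SD (error bars), n = 3, 3, 3 and 2. The star marks the library labelled OCI-AML3-FLT3-ITD control replicate 2, whose FLT3 level of 53.4 lay below the 178 and 203 of the other FLT3-ITD controls.

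The largest falls in OCI-AML3 were in MS4A6A, LGALS12, CSF1R, RNASE1, WNT7B, IGFBP5, MYBPH, SLC12A3, GBGT1 and RHEX. CSF1R, the receptor of the macrophage growth factor, fell by 6.57 (SE 0.44) on the log2 scale, from 6.81 ± 0.921 to 0.0699 ± 0.00698 CPM, and LGALS12, a galectin, fell by 6.64 (SE 0.15). The largest rises were in DNASE2, CTTN, SYNE1, HMOX1, TREM1, AQP3, EPAS1, CDKN2B, TRANK1 and PTGS2. DNASE2, a lysosomal nuclease, rose from 0.0915 ± 0.0174 to 9.55 ± 0.839 CPM (log2 fold change 6.67, SE 0.66). CTTN, a regulator of cortical actin, rose from 6.82 ± 0.88 to 149.5 ± 3.51 CPM, and EPAS1, a hypoxia-inducible transcription factor, from 48.2 ± 1.04 to 462 ± 16.4 CPM. GBGT1 and RHEX share 16.8% and 19.3% of their exon length with another gene, so part of their counts is uncertain.

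Of 18908 genes tested, 3742 were higher and 4074 lower with FHD-286 in OCI-AML3 at an adjusted p under 0.05 (edgeR quasi-likelihood test), and 1469 and 1232 of them changed at least 2-fold. Without the library labelled OCI-AML3-FLT3-ITD control replicate 2, which is in neither group of this comparison, 5412 were higher and 5561 lower. With library totals in place of composition factors the split was 5161 higher and 3025 lower, and the median of all genes moved to 0.17 from 0.01.

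Growth and replication genes fell together in OCI-AML3. Of 46 nucleolar and growth targets of MYC, 44 fell and 1 rose (45 called adjusted over the list alone), with a median log2 fold change of -0.93. TMEM97 fell by 1.51, SORD by 1.33 and NOP2, a nucleolar RNA methyltransferase, by 0.91, while HK2, a hexokinase, rose by 0.64. Of 30 S phase genes, 27 fell and none rose (29 adjusted over the list alone; median -1.03), among them the nuclease gene EXO1 (-1.31) and the replication factor genes GINS2 (-1.38) and CDC45 (-1.48). By camera with a preset correlation, the adjusted p was 4.34e-27 for the MYC targets and 1.28e-18 for the S phase genes. They were 0.160 and 0.176 as adjusted p with an estimated correlation. TMEM97 and NOP2 share 11.9% and 54.4% of their exon length with other genes.

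Most called myeloid genes also fell in OCI-AML3. Of 27 monocyte and macrophage markers, 14 fell and 6 rose (20 adjusted over the list alone; median -1.16), with lysozyme, LYZ, at -3.84, the Fc receptor gene FCGR2A at -1.39, the protease gene CTSS at -1.81 and the scavenger receptor gene CD36 at 0.87. List member TREM1 was among the largest rises above. Mean CPM also went up for CEBPB (27.1 to 97.6), KLF4 (12.3 to 23.2) and MNDA (249.6 to 374.5). Of 17 granule and neutrophil precursor genes, 12 fell and 3 rose (15 adjusted over the list alone; median -0.92). The granule protease gene PRTN3 fell from 1944 ± 157 to 153 ± 2.76 CPM, MS4A3 by 1.79 and the chemokine receptor gene CXCR2 by 2.91. CAMP, an antimicrobial peptide gene, had 2 counts in the controls and 1022 with FHD-286, a ratio of 389 with a 95% counting interval of 108 to 3220. Of 25 haematopoietic transcription factors, 13 fell and 4 rose (19 adjusted over the list alone; median -0.41), with FLI1 at -1.36, LYL1 from 67.8 ± 6.95 to 16.9 ± 1.73 CPM and GFI1 at 0.56. Of 13 AML stem and blast surface markers, 8 fell and 1 rose (9 adjusted over the list alone; median -1.11), with the cytokine receptor genes CSF2RB at -1.82 and CSF3R at -1.10, LILRB4 at -2.12 and HAVCR2 at 1.49. By camera the adjusted p was 3.39e-05, 3.15e-06, 0.000114 and 7.5e-05 for these 4 lists. These became 0.176, 0.0956, 0.0956 and 0.158 as adjusted p with an estimated correlation, and in that test only the surface marker list was called without the library labelled OCI-AML3-FLT3-ITD control replicate 2 (adjusted p 0.0058). LYZ and LILRB4 share 34.0% and 13.0% of their exon length with other genes.

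Histone and HOX genes rose in OCI-AML3. Of 18 replication-dependent histone genes, 11 rose and 1 fell (13 adjusted over the list alone; median 1.30), with H2BC4 at 2.84, H2BC12 at 1.65, H2BC11 at 1.82 and H1-5 at -1.25. Of 20 HOXA, HOXB and MEIS1 genes, regulators of progenitor identity, 11 rose and 4 fell (17 adjusted over the list alone; median 0.39), with HOXB5 at 2.65, HOXA13 at 0.63, HOXB2 at 0.75 and HOXA3 at -1.84. Of 21 ERK pathway output genes, 11 rose and 5 fell (19 adjusted over the list alone; median 0.67), with EGR3 at 2.03, DUSP2 at -1.65 and FOSL1 at -1.51. Camera gave an adjusted p of 0.000114, 0.00801 and 0.0258. These were 0.255, 0.239 and 0.255 as adjusted p with an estimated correlation. HOXA3 shares 17.9% of its exon length with other genes.

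Smaller calls in OCI-AML3 covered 3 further lists. Of 4 class II antigen presentation genes, CTSS and CD74 fell (2 adjusted over the list alone; adjusted p 0.0019 by camera, adjusted p = 0.0956 with an estimated correlation). Of 23 cholesterol synthesis genes, 10 fell and 1 rose (12 adjusted over the list alone; adjusted p 0.00801 by camera, adjusted p = 0.710 with an estimated correlation), and 18 fell and 2 rose without the library labelled OCI-AML3-FLT3-ITD control replicate 2. Of 32 ribosomal protein genes, 12 fell (12 adjusted over the list alone; adjusted p 0.0206 by camera, adjusted p = 0.795 with an estimated correlation), with a median of -0.24, and this call ended with upper-quartile scaling (-0.17), with library totals (-0.08), with a stricter filter (-0.20) and without the library labelled OCI-AML3-FLT3-ITD control replicate 2 (-0.24, adjusted p 0.0737 by camera), although 23 genes were lower there.

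FHD-286 also lowered MYC and SPI1 in OCI-AML3-FLT3-ITD. MYC fell from 665 ± 83.7 to 189 ± 16.0 CPM (SD, n = 3 and 2; log2 fold change -1.82, SE 0.11) and SPI1 from 290 ± 23.1 to 23.6 ± 0.654 CPM (log2 fold change -3.62, SE 0.12). SMARCA2 rose by 0.30 (SE 0.08). SMARCA4 had a log2 fold change of -0.13 and FLT3 one of 0.23, and neither passed the test. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 2.75e-06 for MYC, 8.04e-08 for SPI1 and 0.0204 for SMARCA2, against 0.344 for SMARCA4 and 0.698 for FLT3. Without the library labelled OCI-AML3-FLT3-ITD control replicate 2, SMARCA4 was called at -0.20 (adjusted p 0.033, edgeR) and FLT3 was at -0.16.

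The largest falls in the FLT3-ITD line were in RNASE1, CSF1R, NXF3, ATP10A, IGFBP5, HSH2D, LGALS12, RHEX, CD44 and HGF. CSF1R fell by 7.17 (SE 0.53) and LGALS12 fell by 6.03 (SE 0.17). Some of these changes rested on the library labelled OCI-AML3-FLT3-ITD control replicate 2. Without it NXF3 moved from -6.78 to -2.09, ATP10A from -6.69 to -3.35, HSH2D from -6.09 to -2.62, CD44, an adhesion receptor, from -5.51 to -3.19, and HGF, a growth factor, from -5.28 to -1.77. RNASE1 moved from -7.50 to -5.45 and IGFBP5 from -6.56 to -5.21. The largest rises were in DNASE2, CTTN, AQP3, PTK2, EPAS1, SYNE1, HOXB5, RHBDF1, HMOX1 and HFE. CTTN rose from 4.69 ± 3.03 to 116 ± 0.134 CPM (log2 fold change 4.63, SE 0.37), and PTK2, the focal adhesion kinase gene, from 4.01 ± 1.62 to 35.7 ± 0.0525 CPM. CTTN was at 5.29 and EPAS1 moved from 3.09 to 4.03 without the library labelled OCI-AML3-FLT3-ITD control replicate 2.

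In the FLT3-ITD line 2957 genes were higher and 2810 lower with FHD-286 at an adjusted p under 0.05 (edgeR quasi-likelihood test), 878 and 1147 of them at least 2-fold. The counts were 4619 and 4521 without the library labelled OCI-AML3-FLT3-ITD control replicate 2. They were 1530 and 1378 without treated replicate 1 and 1886 and 1578 without treated replicate 2, fits in which the lone treated library was assumed to vary like the other groups. With library totals the split was 4032 higher and 2254 lower.

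Myeloid lists fell in the FLT3-ITD line. Of 27 monocyte and macrophage markers, 18 fell and 1, CD36, rose (23 adjusted over the list alone; median -1.51), with LYZ at -3.05 and FCGR2A at -1.51. Of 17 granule and neutrophil precursor genes, 12 fell and 3 rose (16 adjusted over the list alone; median -1.50), with PRTN3 at -3.15, MS4A3 at -2.53, the peroxidase gene MPO at -3.14 and CAMP at 5.18. Of 25 haematopoietic transcription factors, 16 fell and 1, ELF1, rose (17 adjusted over the list alone; median -0.70), with FLI1 at -1.86 and LYL1 at -1.75. Of 13 AML stem and blast surface markers, 9 fell (9 adjusted over the list alone; median -1.70), with CSF2RB at -3.46, CSF3R at -1.70 and LILRB4 at -2.73, and the list's median was -0.93 without the library labelled OCI-AML3-FLT3-ITD control replicate 2. The adjusted p by camera was 6.19e-14, 2.77e-12, 9.27e-12 and 2.84e-08 for these 4 lists. These 4 calls held with an estimated correlation, at adjusted p 0.0402, 0.0112, 0.0112 and 0.0402, and no other list call from all 11 libraries did in any comparison.

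Other lists moved in the FLT3-ITD line as well. Of 46 nucleolar and growth targets of MYC, 35 fell (39 adjusted over the list alone; median -0.60), with SORD at -1.07, WDR74 at -1.10 and TMEM97 at -0.76. Of 30 G2 and M phase genes, 17 rose and none fell (22 adjusted over the list alone; median 0.41), with the mitotic kinesin gene KIF11 at 0.71, DLGAP5 at 0.82 and ANLN at 0.61. Of 20 HOXA, HOXB and MEIS1 genes, 11 rose (11 adjusted over the list alone; median 0.43), and of 25 p53 target genes, 10 rose and 1, SESN2, fell (13 adjusted over the list alone; median 0.31), with TP53INP1 at 1.80. Of 22 ATF4 stress response genes, 10 fell (12 adjusted over the list alone; median -0.91), and 21 fell without the library labelled OCI-AML3-FLT3-ITD control replicate 2. Of 32 ribosomal protein genes, 22 fell (27 adjusted over the list alone; median -0.42), and of 4 class II antigen presentation genes, CTSS and CD74 fell (2 adjusted over the list alone). By camera the adjusted p was 9.94e-14 for the MYC targets, 1.59e-06 for G2 and M phase, 1.89e-05 for HOX, 0.00106 for p53, 0.000765 for ATF4, 1.65e-06 for ribosomal protein and 0.00251 for class II genes. They were, in this order, 0.326, 0.326, 0.0749, 0.544, 0.602, 0.585 and 0.0661 as adjusted p with an estimated correlation. In that test the ATF4 and HOX lists were called without the library labelled OCI-AML3-FLT3-ITD control replicate 2 (adjusted p 0.0174 and 0.0408), and the other 5 were not. WDR74 shares 22.3% of its exon length with other genes.

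**Figure D3:**
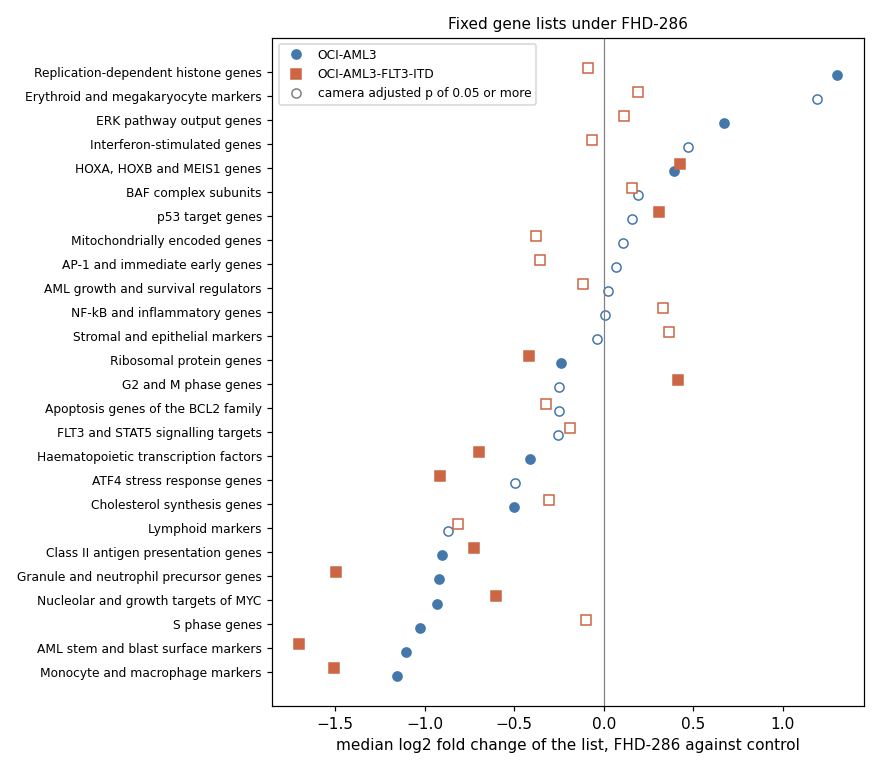
Median log2 fold change under FHD-286 of each gene list fixed before the data were examined, in OCI-AML3 (circles) and OCI-AML3-FLT3-ITD (squares), with filled symbols for a camera adjusted p under 0.05. The S phase genes lie at -1.03 in OCI-AML3 and at -0.10 in OCI-AML3-FLT3-ITD.

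The remaining lists did not pass camera's test. In OCI-AML3 these were G2 and M phase genes (0 higher and 10 lower of 30, adjusted p 0.0587), interferon-stimulated genes (10 and 6 of 28, adjusted p 0.0698), AML growth and survival regulators (4 and 6 of 19), AP-1 and immediate early genes (6 and 7 of 20), BCL2 family genes (4 and 6 of 14) and ATF4 stress response genes (3 and 8 of 22). BAF complex subunits (9 and 6 of 25), FLT3 and STAT5 signalling targets (3 and 5 of 15), NF-kB and inflammatory genes (6 and 4 of 23) and p53 target genes (8 and 6 of 25) did not either. Markers of other cell types were few: 4 erythroid and megakaryocyte markers (2 higher), 7 lymphoid markers (1 higher and 2 lower) and 9 stromal and epithelial markers (2 higher and 1 lower) were measured. None of 13 mitochondrially encoded genes was called by edgeR. In OCI-AML3 2 G2 and M phase genes were higher and 19 lower, 5 ATF4 genes higher and 14 lower, and 8 NF-kB genes higher and 8 lower, without the library labelled OCI-AML3-FLT3-ITD control replicate 2. In the FLT3-ITD line S phase genes (3 higher and 3 lower of 30; adjusted p 0.630 by camera) and replication-dependent histone genes (4 and 1 of 18; adjusted p 0.527) did not pass. Without the library labelled OCI-AML3-FLT3-ITD control replicate 2 the histone list passed there (median 0.21, adjusted p 0.00997 by camera), as did the AP-1 (-0.34), BCL2 family (-0.45), ERK output (0.16), lymphoid (-1.24) and erythroid (0.87) lists. With an estimated correlation in that fit only the lymphoid call held (adjusted p 0.0408), and the others gave 0.367, 0.291, 0.123, 0.219 and 0.123 in the order named. The S phase list did not (4 genes higher and 16 lower; median -0.19, adjusted p 0.0719 by camera). The median, mean and test differed in sign in OCI-AML3 for the AML growth, AP-1 and stromal lists, and in the FLT3-ITD line for the interferon, histone and stromal lists, none of which was called by camera with all 11 libraries.

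The effects of FHD-286 in both lines were correlated across genes, with a Pearson r of 0.666 and a Spearman rho of 0.638 over 18908 genes, which are not independent replicates; each line had its own controls. Of the genes called in both lines, 2129 were higher in both and 2080 lower in both, against 585 and 605 for independent lists, and 92 moved in opposite directions. Without the library labelled OCI-AML3-FLT3-ITD control replicate 2, r was 0.741, and 3503 were higher in both (1340 for independent lists), 3592 lower in both (1347) and 309 opposite. The shared calls in the same direction were then 7095, and they were 2502 and 2786 without FLT3-ITD FHD-286 replicates 1 and 2, with r at 0.602 and 0.551. With no low-count filter r was 0.288.

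The interaction of line and treatment asked where FHD-286 acted differently in the FLT3-ITD line. It uses the same controls as the comparison of untreated lines below, with opposite sign. A gene measured too high in the FLT3-ITD controls would look higher untreated and more negative here, so these results are not independent. SPI1 fell further in the FLT3-ITD line, by 0.78 on the log2 scale (SE 0.13, n = 3, 3, 3 and 2), while MYC differed by 0.06 (SE 0.14) and was not called. Among called genes with an average log2 CPM of at least 2, the most negative differences were in CRISPLD2 (-3.59), ART3 (-2.51), CEBPB (-2.46), CD101 (-2.37), DDIT4 (-2.31) and FAM43A (-2.31). CRISPLD2 was at -2.87 and FAM43A at -1.62 without the library labelled OCI-AML3-FLT3-ITD control replicate 2. CEBPB, a myeloid transcription factor, went from 27.1 ± 1.63 to 97.6 ± 1.63 CPM in OCI-AML3 and from 76.1 ± 20.8 to 49.8 ± 14.3 CPM in the FLT3-ITD line. The most positive differences among the same genes were in SHANK1 (1.58), KIAA0040 (1.53), ICAM1 (1.47), BIN1 (1.43), F2RL3 (1.40) and TDRD7 (1.38). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p of the difference was 0.0128 for SPI1, 0.00273 for CEBPB and 0.870 for MYC. DDIT4, ICAM1, CEBPB and CD101 share 41.2%, 23.6%, 11.8% and 10.3% of their exon length with other genes.

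The difference between lines was more positive in 375 genes and more negative in 260 (edgeR quasi-likelihood test, adjusted p under 0.05), 55 and 147 of them by at least 1 on the log2 scale. Without the library labelled OCI-AML3-FLT3-ITD control replicate 2 the counts were 1797 and 1380, 168 and 431 of them by at least 1 on the log2 scale. Without FLT3-ITD control replicate 1 the counts were 742 and 458. They were 112 and 98, 148 and 117, and 152 and 145 without OCI-AML3 control replicates 1, 2 and 3, and 110 and 110, 115 and 106, and 71 and 114 without treated OCI-AML3 replicates 1, 2 and 3. Without treated FLT3-ITD replicates 1 and 2 they were 45 and 60, and 100 and 84. With upper-quartile scaling the split was 308 and 374, and the median of all genes moved to -0.11.

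Cell cycle genes differed between the lines. Of 30 S phase genes, 21 had a more positive effect in the FLT3-ITD line and none a more negative one (30 adjusted over the list alone; median 0.87), with EXO1 at 1.20, GINS2 at 1.14 and RRM2, a ribonucleotide reductase subunit gene, at 0.82. EXO1 went from 76.8 ± 3.77 to 30.9 ± 0.255 CPM in OCI-AML3 and from 73.1 ± 3.28 to 67.5 ± 4.26 CPM in the FLT3-ITD line. Of 30 G2 and M phase genes, 14 had a more positive effect (28 adjusted over the list alone; median 0.60), with NUSAP1 at 0.77, KIF11 at 0.73 and BUB1B at 0.80. All 30 G2 and M phase genes and 29 S phase genes were more positive without the library labelled OCI-AML3-FLT3-ITD control replicate 2. Camera gave an adjusted p of 5.13e-45 and 6.64e-27. Both were 0.0808 as adjusted p with an estimated correlation, and 0.0191 and 0.0131 in that test without the library labelled OCI-AML3-FLT3-ITD control replicate 2. NUSAP1, RRM2 and BUB1B share 62.2%, 20.2% and 10.2% of their exon length with other genes.

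Monocyte, histone and interferon lists went the other way. Of 27 monocyte and macrophage markers, 5 had a more negative effect in the FLT3-ITD line and 1, LYZ (0.79), a more positive one (9 adjusted over the list alone; median -0.88), with KLF4 at -1.18, CEBPB at -2.46 and MNDA at -1.20. Mean CPM of KLF4, CEBPB and MNDA went up with FHD-286 in OCI-AML3 and down in the FLT3-ITD line. KLF4 went from 12.3 to 23.2 and from 14.8 to 12.3 CPM, and MNDA from 249.6 to 374.5 and from 194.5 to 126.9 CPM. Of 18 histone genes, H2BC4 (-2.19), H2BC8 (-2.81) and H4C8 (-2.37) were more negative (10 adjusted over the list alone, median -1.07). Of 28 interferon-stimulated genes, IFIT2 (-3.85), IFIT3 (-1.03) and IFIT1 (-1.48) were (10 adjusted over the list alone, median -0.54). Mean CPM of these 3 IFIT genes was higher with FHD-286 in both lines. Their fold rise was smaller in the FLT3-ITD line, from a higher untreated level, and their treated level was higher there. IFIT1 went from 0.185 to 1.56 CPM in OCI-AML3 and from 0.737 to 2.22 CPM in the FLT3-ITD line. IFIT2 went from 0.0622 to 3.70 CPM in OCI-AML3 and from 1.32 to 5.22 CPM in the FLT3-ITD line. Its OCI-AML3 controls held 11 counts in all, close to the limit of 3 counts in a library. More negative genes numbered 12 monocyte, 11 histone and 10 interferon genes without the library labelled OCI-AML3-FLT3-ITD control replicate 2. The adjusted p by camera was 1.29e-05, 5.47e-08 and 0.00441. These were 0.183, 0.183 and 0.210 as adjusted p with an estimated correlation, and 0.00972, 0.119 and 0.0301 in that test without that library. Of 22 ATF4 stress response genes, DDIT4 and CTH (-1.44) were more negative (4 adjusted over the list alone; adjusted p 0.0136 by camera, adjusted p = 0.661 with an estimated correlation), and 15 were without the library labelled OCI-AML3-FLT3-ITD control replicate 2. Mean DDIT4 went from 10.7 to 26.8 CPM in OCI-AML3 and from 110.6 to 55.7 CPM in the FLT3-ITD line. Mean CTH went from 6.63 to 5.98 and from 19.4 to 6.45 CPM, so its treated levels were close and its controls differed. Of 23 cholesterol synthesis genes none was called by edgeR (1 adjusted over the list alone; median 0.21, adjusted p 0.0251 by camera, adjusted p = 0.661 with an estimated correlation), and without that library 19 were more positive (median 0.59). With an estimated correlation and without that library the adjusted p by camera was 0.0131 for ATF4 and 0.00972 for cholesterol genes. The ATF4 and cholesterol calls were lost without FLT3-ITD control replicate 1 (adjusted p 0.319 and 0.302 by camera) or 3 (0.227 and 0.325). In both of these fits the library labelled OCI-AML3-FLT3-ITD control replicate 2 weighed more in its group. IFIT2 shares 10.3% of its exon length with other genes.

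Between the untreated lines FLT3 was higher in the FLT3-ITD controls, at 145 ± 80.2 against 42.0 ± 1.16 CPM (SD, n = 3 and 3; log2 fold change 1.79, SE 0.36), and the fold change was 2.18 without the library labelled OCI-AML3-FLT3-ITD control replicate 2. MYC was lower, with a log2 fold change of -0.31 (SE 0.10), SMARCA2 was higher by 0.27 (SE 0.08), and SPI1 (-0.14) and SMARCA4 (-0.22) were not called. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 0.00592 for FLT3, 0.0367 for MYC and 0.0219 for SMARCA2, against 0.262 for SPI1 and 0.0753 for SMARCA4.

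The genes furthest above OCI-AML3 were WLS, WT1, FKBP10, UNC5B, MEI1, SLC12A3, TGFBI, CDC42EP1, LTK and SLC39A4. WT1 had a log2 fold change of 7.88 (SE 1.46), with 21.8, 0.20 and 19.9 CPM in FLT3-ITD control replicates 1, 2 and 3 against 0.0578 ± 0.0128 CPM in OCI-AML3 controls. WLS had 1 count in the OCI-AML3 controls and 2105 in the FLT3-ITD controls, a ratio of 1670 with a 95% counting interval of 299 to 66000. The genes furthest below were GABBR2, MFAP3L, FUCA1, SRGAP1, VEGFC, WNT7B, DLX2, TBXAS1, PDGFD and EPAS1. A gene was named only if the library labelled OCI-AML3-FLT3-ITD control replicate 2 also lay outside the range of the OCI-AML3 controls. Genes on which that library lay within this range were left out, however far the other FLT3-ITD controls lay from it. GABBR2, a subunit gene of the GABA type B receptor, was at -3.01 (SE 0.91) and at -6.25 without the same library, MFAP3L moved from -2.35 to -3.46, SRGAP1 from -1.97 to -3.39, VEGFC from -1.82 to -3.08, WNT7B from -1.81 to -2.79, DLX2 from -1.75 to -3.13, TBXAS1 from -1.74 to -2.49, PDGFD from -1.73 to -2.62 and EPAS1 from -1.63 to -2.58.

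At an adjusted p under 0.05 (edgeR quasi-likelihood test), 2738 genes were higher and 2551 lower in the FLT3-ITD controls, 1383 and 191 of them at least 2-fold. The excess of higher genes among 2-fold changes was smaller without the library labelled OCI-AML3-FLT3-ITD control replicate 2. The counts there were 4490 and 4733, 1899 and 901 of them at least 2-fold. They were 1582 and 1548 without OCI-AML3 control replicate 1, 1542 and 1372 without replicate 3, and 1797 and 1807 without FLT3-ITD control replicate 3. The split was 3457 higher and 1648 lower with library totals, which moved the median of all genes to 0.11, and 3282 and 1957 with upper-quartile scaling.

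Stress and inflammatory genes were higher in the untreated FLT3-ITD line. The same controls enter the difference between lines under FHD-286 with opposite sign, so the negative ATF4 and interferon differences above are not independent of these. Of 22 ATF4 stress response genes, 21 were higher (22 adjusted over the list alone; median 1.71), with VLDLR at 1.38, DDIT4 at 3.37 and the folate enzyme gene ALDH1L2 at 1.87. Of 28 interferon-stimulated genes, 17 were higher and 1, BST2, was lower (19 adjusted over the list alone, median 0.91). IFIT2 was at 4.35, with 11 counts in the OCI-AML3 controls, SAMD9L at 2.93 and IFIT3 at 1.29. Of 23 NF-kB and inflammatory genes, 16 were higher (16 adjusted over the list alone; median 0.85), with the chemokine gene CXCL8 at 1.78, NFKB2 at 1.25 and TRAF1 at 1.28. By camera the adjusted p was 1.27e-27, 3.06e-07 and 3.99e-06. These were 0.192, 0.124 and 0.343 as adjusted p with an estimated correlation, and 0.00249, 0.0136 and 0.0115 in that test without the library labelled OCI-AML3-FLT3-ITD control replicate 2.

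Further lists differed between the untreated lines. Of 20 AP-1 and immediate early genes, 10 were higher and 2 lower (12 adjusted over the list alone; median 0.37), with KLF10 at 1.66, EGR1 at 1.93 and FOSL1 at -0.91. Of 20 HOXA, HOXB and MEIS1 genes, 10 were higher and 2 lower (13 adjusted over the list alone; median 0.35), with HOXB3 at 0.82 and HOXA10 at -0.34. Of 30 G2 and M phase genes, 17 were higher (19 adjusted over the list alone; median 0.31), with TOP2A at 0.71. Of 46 nucleolar and growth targets of MYC, 28 were lower (30 adjusted over the list alone; median -0.38), with NOP2 at -0.79 and SLC19A1 at -0.97. SLC19A1 lies in a window of chromosome 21 genes with a median difference of -0.68 between the untreated lines, so copy number may account for part of its difference. Of 17 granule genes, 6 were lower and 1, MMP9, was higher (7 adjusted over the list alone), with a median of -0.38 and a mean of 0.02, and ELANE at -1.35. Camera gave an adjusted p of 0.000307, 0.00594, 9.06e-07, 4.86e-15 and 0.0175. These were 0.124, 0.343, 0.343, 0.343 and 0.343 as adjusted p with an estimated correlation. Of 32 ribosomal protein genes 3 were lower (0 adjusted over the list alone by edgeR; adjusted p 0.000999 by camera, adjusted p = 0.851 with an estimated correlation), and 27 were without the library labelled OCI-AML3-FLT3-ITD control replicate 2. Of 23 cholesterol synthesis genes 2 were lower (1 adjusted over the list alone; adjusted p 0.0120 by camera, adjusted p = 0.851 with an estimated correlation), and 20 were without that library. The granule list was not called without that library (adjusted p 0.129 by camera). With an estimated correlation in that fit the HOX and cholesterol lists were called (adjusted p 0.0321 and 0.0185), and the other 5 of this paragraph were not. HOXA10, MMP9, SLC19A1 and HOXB3 share 26.3%, 18.4%, 14.0% and 13.2% of their exon length with other genes.

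The monocyte list did not pass between the untreated lines, with 11 markers higher and 3 lower of 27 (median 0.27, adjusted p 0.0661 by camera), and passed without the library labelled OCI-AML3-FLT3-ITD control replicate 2 (median 0.47, adjusted p 0.000176). AML surface markers (-0.48), lymphoid markers (0.67), mitochondrially encoded (-0.32), p53 target (0.19) and S phase genes (0.21) also passed in the fit without that library and not with all 11. With an estimated correlation in that fit only the surface marker call held (adjusted p 0.0136 by camera). The others gave 0.0558 for monocyte, 0.0697 for lymphoid, 0.692 for mitochondrially encoded, 0.114 for p53 and 0.670 for S phase genes. The median, mean and test differed in sign for the AML growth, BCL2 family, ERK output, erythroid, FLT3 and STAT5, transcription factor, mitochondrially encoded and stromal lists, none of them called by camera with all 11 libraries.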

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

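The tests of the position of the library labelled OCI-AML3-FLT3-ITD control replicate 2, and of the S phase difference without it, were chosen after the result was seen, as were the list tests without it with an estimated correlation.

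The library labelled OCI-AML3-FLT3-ITD control replicate 2 lay near the OCI-AML3 controls. Over 151 markers that separate the lines in the treated libraries, its median position was 7.1% (quartiles -10.3 and 24.3) of the way from the OCI-AML3 controls to the other FLT3-ITD controls, or 8.34% over 145 markers that also separate the untreated libraries. That argues against RNA quality alone, which would leave markers above 50%, while 12 markers near 0 in OCI-AML3 sat at 0.0387%, against a mixture of both lines. No OCI-AML3 control was out of place (highest 0.726%), against a swap between these groups. OCI-AML3 cells under a wrong label or from outside the series may account for most of it. However, the 68 markers higher in the FLT3-ITD line sat at 21.2% and the 83 lower ones at -1.27%, so what the library holds stays open. Of 10522 genes, 46 were at least 2-fold above and 23 below all 5 other untreated libraries. Such counts were not made for any other library, so whether these are unusual cannot be told.

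S phase genes differed between the lines under FHD-286 by a median of 0.87 on the log2 scale. The difference was 0.77 without the library labelled OCI-AML3-FLT3-ITD control replicate 2, at least 0.78 under 3 other scalings, and 0.91 (quartiles 0.74 and 1.02) after removing trends on GC content and gene length, against each of these as the whole cause. A difference in how the lines' cell cycle responds to FHD-286 may account for it, as a hypothesis, since cycling was not measured and camera with an estimated correlation gave an adjusted p of 0.0808 with all 11 libraries.

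The effect of FHD-286 was more positive in the FLT3-ITD line in 375 genes and more negative in 260 by edgeR's interaction test, or 1797 and 1380 without the library labelled OCI-AML3-FLT3-ITD control replicate 2. Of the lists, G2 and M phase genes differed by 0.60, monocyte markers by -0.88, histone genes by -1.07, interferon-stimulated genes by -0.54 and ATF4 genes by -0.24 (-0.55 without that library). None of these list calls held with an estimated correlation and all 11 libraries, and the histone call did not hold in that test without that library either. MYC targets differed by 0.34, transcription factors by -0.28 and granule genes by -0.45, with adjusted p 1.57e-10, 0.000266 and 0.00441 by camera, and 0.316, 0.132 and 0.183 as adjusted p with an estimated correlation. Surface markers differed by -0.60 (-0.06 without that library), ERK output genes by -0.39 (-0.11), AP-1 genes by -0.11 (-0.07) and cholesterol genes by 0.21 (0.59), with 0.279, 0.279, 0.210 and 0.661 as adjusted p with an estimated correlation. Ribosomal protein (-0.17), mitochondrially encoded (-0.45) and p53 target genes (0.20) were called by camera with all 11 libraries and not without that library (adjusted p 0.233, 0.265 and 0.447), and their adjusted p with an estimated correlation was 0.670, 0.658 and 0.658.

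Single genes of the lists and rules differed between the lines in the same interaction test, given here as the log2 difference. It was negative for SPI1 (-0.78), FLI1 (-0.50), GFI1 (-0.99), CSF2RB (-1.64), CSF3R (-0.60), KLF4 (-1.18), CEBPB (-2.46), MNDA (-1.20), MPO (-1.64) and MS4A3 (-0.74). It was also negative for CRISPLD2 (-3.59), ART3 (-2.51), CD101 (-2.37), FAM43A (-2.31), DDIT4 (-2.31), CTH (-1.44), CDKN2B (-1.28), TRANK1 (-1.18), EGR1 (-2.28) and KLF10 (-0.73). Further negative values were those of IFIT1 (-1.48), IFIT2 (-3.85, with 11 counts in the OCI-AML3 controls), IFIT3 (-1.03), H2BC4 (-2.19), H2BC8 (-2.81) and H4C8 (-2.37). The log2 difference in the IFIT genes was a smaller fold rise in the FLT3-ITD line, from a higher untreated level. The log2 difference was positive for EXO1 (1.20), GINS2 (1.14), CDC45 (0.93), RRM2 (0.82), NUSAP1 (0.77), KIF11 (0.73), BUB1B (0.80), ANLN (0.55), DLGAP5 (0.61) and TOP2A (0.59). It was also positive for LYZ (0.79), TMEM97 (0.75), SHANK1 (1.58), KIAA0040 (1.53), ICAM1 (1.47), BIN1 (1.43), F2RL3 (1.40) and TDRD7 (1.38).

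For the number of genes called between treated and control OCI-AML3 libraries (7816) and between the untreated lines (5289), the 10 splits of 6 libraries are too few for a share under 0.05. In each case 1 split, the real one, called as many by edgeR, and the highest of the other splits called 0.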

How the results depend on the processing

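The alternatives for the counts were planned, and the list tests without the doubted library with an estimated correlation were chosen after the result was seen. Requiring a log2 fold change of at least 1 as well left 1469 higher and 1232 lower genes in OCI-AML3, 878 and 1147 in OCI-AML3-FLT3-ITD, 55 and 147 for the difference between lines, 1383 and 191 between untreated lines, and 1310 shared calls, by construction. With that threshold and without the library labelled OCI-AML3-FLT3-ITD control replicate 2, the comparisons in this order gave 1757 and 1378, 1147 and 1328, 168 and 431, and 1899 and 901. Fitting only the groups compared gave 5677 higher and 5656 lower genes in OCI-AML3, 730 higher and 888 lower in the FLT3-ITD line, and 1078 and 658 between untreated lines; the last 2 fits took their spread from groups that hold the library labelled OCI-AML3-FLT3-ITD control replicate 2. Library totals gave 1648 lower genes between untreated lines, no filter gave 401 more negative differences, and DESeq2 gave 788 more positive and 653 more negative differences; the cause was not tested. The correlation of effects was 0.288 with no filter and 0.722 with the stricter filter, since the filters change which low-count genes enter. With the replicate number as a block the differences were 203 and 146; deviations of same-numbered libraries correlated at -0.0288 to 0.122, too low to establish that the numbers pair the samples, although 7 of 11 libraries correlated best with one of their own number.

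Leaving out each library in turn gave 2872 to 5412 higher and 3107 to 5561 lower genes in OCI-AML3, 1530 to 4619 and 1378 to 4521 in the FLT3-ITD line, 45 to 1797 and 60 to 1380 for the difference, and 1542 to 4490 and 1372 to 4733 between untreated lines. The correlation ran from 0.551 to 0.741 and the shared calls from 2502 to 7095. The highest of each came without the library labelled OCI-AML3-FLT3-ITD control replicate 2. Without it MT-ND3 and MT-ND6 changed sign between untreated lines, to -0.24 and -0.27 (edgeR adjusted p 0.0297 and 0.0261), against highest values of 0.47 and 0.37 without FLT3-ITD control replicate 3. Mitochondrially encoded genes took 8.85% of the counts of the library left out first, against 4.82% and 4.48% in FLT3-ITD control replicates 1 and 3, so the sign rested on that library. The cause of its high share was not tested. With an estimated correlation 45 list calls were lost, and with fry 12 were lost and 15 gained. List calls lost were 4 with the stricter filter, up to 1 in each other scaling, filter or block fit, and 0 to 5 without each library, where up to 13 were gained. Of tests of named genes, 54 calls were lost in the fits of only the groups compared, 18 with the block and up to 13 in other scalings, filters or DESeq2. Without 1 library 0 to 54 were lost, most without FLT3-ITD FHD-286 replicates 1 and 2 (54 and 51), and a minimum log2 fold change of 1 removed 104 by construction. Low-count genes remain limited by depth, where 3 counts are at most 0.0548 CPM.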

Other observations

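The test of gene copy number and the window settings were chosen after the result was seen. Neighbouring genes differed together between the untreated lines in parts of chromosomes 6, 16, 18 and 21. With the library labelled OCI-AML3-FLT3-ITD control replicate 2 left out, 8870 coding genes were taken in 210 windows of 40 genes, or 42 to 79 at the end of a chromosome, and 10 windows had a median log2 difference of at least 0.4 in size, 8 higher and 2 lower in the FLT3-ITD line. Of these, 5 lay side by side on chromosome 6, with medians of 0.694, 0.605, 0.592, 0.616 and 0.628, and 1 on chromosome 16 had 0.757. Chromosome 18 had 1 window at -0.453 followed by others at 0.581 and 0.555, and chromosome 21 had 1 at -0.678, which holds RUNX1 and ERG, transcription factors of blood cells, while BCL2, an apoptosis inhibitor gene, lay in the last window of chromosome 18.

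No window passed in any of 1000 shuffles of gene order, where the largest shift was 0.333. Under FHD-286, 2 windows passed the same shift in OCI-AML3, at 0.408 on chromosome 5 and 0.418 on chromosome 8, and 0 in the FLT3-ITD line. Shifts just past 0.4 can therefore arise within 1 line. A trend on GC content as the cause was argued against, since 100% of the windows kept a shift of at least 0.3 after its removal. Differences in gene copy number between the lines are a candidate explanation. In the treated libraries 100% of the windows recurred with the same sign and a shift of at least 0.3, the weakest at -0.318 on chromosome 18. These libraries come from the same lines, so any other lasting regional difference would recur too, and recurrence cannot single out copy number. A gain from 2 to 3 copies would give 0.585 on the log2 scale, a value that concerns the higher windows only. The shift recurred in 0 of the 10 windows in the library labelled OCI-AML3-FLT3-ITD control replicate 2. With windows of 20 to 80 genes and shifts of 0.3 to 0.5, between 2 and 26 windows passed, and 22 of the 26 recurred. Copy number itself was not measured.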
